A study of Homo sapiens with 6 samples.

How the data were processed

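Gene expression was measured in 6 libraries of SW620, a human colorectal cancer cell line established from a lymph node metastasis. In 3 libraries the cells stably carried a short hairpin RNA against ECM1 (shECM1), and in 3 they carried a negative control hairpin (shNC). Groups and replicate numbers were taken from the sample titles. The columns of the deposited table carry short names built from a letter and a number. They were matched to the sample titles by those letters and numbers, before the values of ECM1 or CCL20 were looked up. This match is an inference from the names, and if the letters stood for the opposite groups, every direction given here would be reversed.

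The authors deposited 1 table of raw counts, with 1 whole-number count per gene and library and no values for single cells. Per the submitters' processing notes, fastp, STAR, featureCounts, DESeq2 and Seurat were used with the human builds GRCh38 and hg38. Their roles, versions, settings and annotation release, and whether counting used strand, are not given in the sources used here. Per the labels' protocols, total RNA was extracted, and the same protocols also describe droplet single-cell libraries. Whether each deposited column is a bulk library or a sum over cells is not stated, and the columns were analysed as 1 library each. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

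The table had 20476 gene rows, and 0 of them named no gene. Symbols were found for 20462 identifiers and not for 14. Of the rows, 19715 were protein-coding genes in GENCODE release 29 (build GRCh38), which gave coordinates and transcript GC content for 20244 identifiers. Near-identical gene copies share reads, and counts of such genes are reported as uncertain.

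Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the group as design, library sizes were scaled by trimmed mean of M values (TMM), and groups were compared with the quasi-likelihood test (glmQLFit and glmQLFTest) with no covariate. P-values were adjusted by Benjamini-Hochberg over the 12576 genes tested, with a threshold of 0.05. A log2 fold change is shECM1 minus shNC, and its standard error (SE) is the size of the fold change divided by the square root of the F statistic. Levels are TMM-normalised CPM, which are counts scaled to 1 common library total, given as mean ± SD with n = 3 unless stated. Principal components used log2 CPM with a prior count of 2.

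Before the data were examined, 36 gene lists were fixed. They covered chemokine and NF-kB signalling, growth factor signalling, matrix and adhesion, cell cycle, metabolism, stress responses, intestinal cell types, and markers of fibroblasts, immune cells, endothelium and embryonic kidney cells. The 32 lists with at least 5 tested members were compared with camera (limma 3.58.1) on voom-weighted log2 CPM. The preset inter-gene correlation was 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. Within a list, genes were also adjusted over the list alone.

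The rule for named genes, fixed at the same time, took ECM1 and CCL20, then the 10 largest rises and 10 largest falls among called genes. Such genes needed a mean log2 CPM of at least 1, no overlap between the groups and a proper gene symbol. Where 0 genes were called, it took the 5 smallest p-values in each direction. For each list it took the 2 members of highest expression where 0 passed. Because edgeR called 0 genes, the part of the rule for rises and falls was also applied to the calls of DESeq2, a step chosen after edgeR's result was seen. Other list members that are named were chosen after their values were seen.

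Alternatives fixed beforehand were DESeq2-type size factors (RLE), upper-quartile factors and library size only, no count filter, a count of at least 50 in at least 3 samples, DESeq2 1.42.0, limma-voom, the replicate number as a block, fold change minimums and leaving out each library. Alternatives chosen after seeing the data were a per-library loess trend on GC content as an offset, robust and non-legacy dispersion fits, and the GC offset, DESeq2, fry and the estimated correlation, each without shNC replicate 2. The procedure was tested on simulated counts for shECM1 against shNC over 12576 genes. It recovered 47.8% of 67 genes changed 1.5-fold, 79.1% of 67 changed 2-fold and 100% of 66 changed 4-fold, all in the right direction. Of 168 calls in all, 8 were among 25 genes shifted together as a list and 9 were false. The recovery rates hold for the simulated counts only and cannot be read as the power in the real libraries. In the real libraries edgeR's quasi-likelihood test called no gene, and ECM1 was uncalled at a log2 fold change of -1.58 (adjusted p = 0.0973). Library totals ran from 9881720 to 16813951 counts. ECM1 rested on 115 to 730 counts per library and CCL20 on 136 to 553.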

Results

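Transcript levels were measured in SW620 colorectal cancer cells with a hairpin against ECM1 and in the same line with a control hairpin, with 3 libraries in each group. ECM1 encodes extracellular matrix protein 1, a secreted glycoprotein. The stated purpose was to examine how ECM1 bears on CCL20, the chemokine ligand of the receptor CCR6. Total counts were 11792872, 13582778 and 14781799 in shNC replicates 1, 2 and 3, and 9881720, 16813951 and 13557415 in shECM1 replicates 1, 2 and 3. Between 14738 and 15107 genes had a count in each library. Mitochondrially encoded genes held 2.97% to 3.28% of counts in shNC and 2.71% to 3.33% in shECM1.

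ECM1, the targeted gene (ENSG00000143369, GRCh38 chromosome 1, 150508062 to 150513789, plus strand), was measured first as a check of the labels. Its level was 36.7 ± 16.7 CPM in shNC and 12.3 ± 3.4 CPM in shECM1 (SD, n = 3 each), a 3-fold lower fitted level in the knockdown. The control libraries stood at 38.8, 19.0 and 52.3 CPM, and the knockdown libraries at 14.8, 13.6 and 8.41 CPM, so the groups did not overlap. These levels came from 265 to 730 counts per control library and 115 to 229 per knockdown library. The log2 fold change was -1.58 ± 0.32 (SE), and edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment did not call it (adjusted p = 0.0973). DESeq2 called it (adjusted p = 0.0256), as did edgeR with no count filter (adjusted p = 0.0139). Without shNC replicate 2, the control library with the lowest ECM1 level, edgeR gave -1.88 (adjusted p = 0.000192).

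CCL20 (ENSG00000115009, GRCh38 chromosome 2, 227805739 to 227817564, plus strand) was at 26.6 ± 12.1 CPM in shNC and 14.2 ± 3.07 CPM in shECM1 (SD, n = 3 each). Control replicates 1, 2 and 3 had 24.6, 15.7 and 39.6 CPM, and knockdown replicates had 13.5, 17.5 and 11.5 CPM. The groups overlapped, because shECM1 replicate 2 lay above shNC replicate 2. The log2 fold change was -0.91 ± 0.28 (SE) and was not called by edgeR (adjusted p = 0.122). DESeq2 called it lower (adjusted p = 0.0246), as did edgeR with no count filter (adjusted p = 0.0486) and edgeR without shNC replicate 2 (log2 fold change -1.16, adjusted p = 0.00251). Without shNC replicate 3, the log2 fold change was -0.50 and was not called (adjusted p = 0.424).

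**Figure D1:**
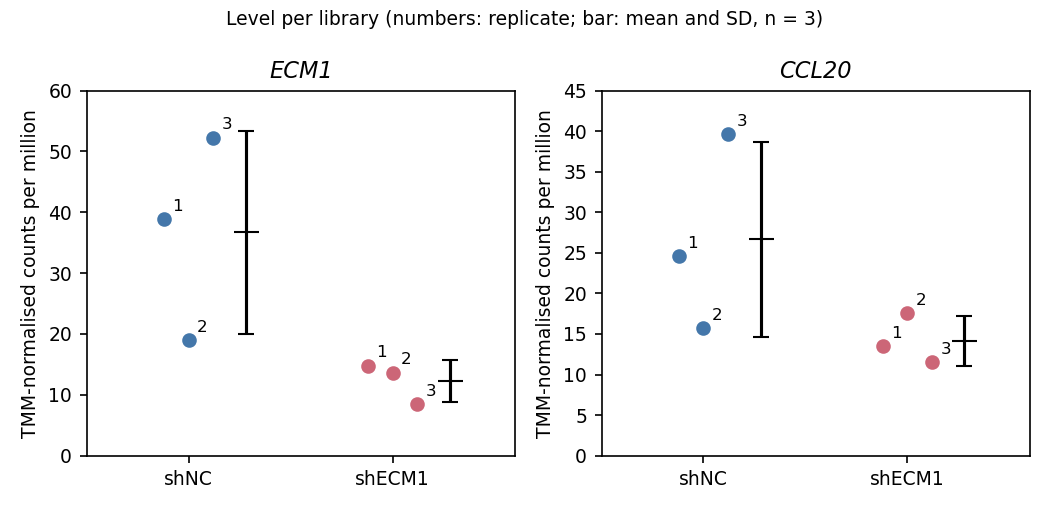
Levels of ECM1 (left) and CCL20 (right) in each library, in TMM-normalised CPM on a vertical axis from 0, with numbers giving the replicate and bars the mean and SD of 3 libraries. ECM1 was at 19.0 CPM or more in shNC and 14.8 CPM or less in shECM1, whereas for CCL20 shECM1 replicate 2 (17.5 CPM) lay above shNC replicate 2 (15.7 CPM).

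The control libraries did not form a tight group. The first principal component held 58.1% of the variance and placed shNC replicates 1 and 3 at -25.2 and -41.3. It placed shNC replicate 2 at 8.64, beside the shECM1 libraries at 16.6, 17.9 and 23.3. Pearson correlations of log2 CPM across genes were 0.976 to 0.990 within shNC, 0.984 to 0.993 within shECM1 and 0.962 to 0.992 between the groups. No pair of libraries agreed within sampling noise, with a chi-square per gene of at least 3.31 where noise alone gives about 1, so none was treated as a second deposit of another. This does not show that they came from separate cultures.

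**Figure D2:**
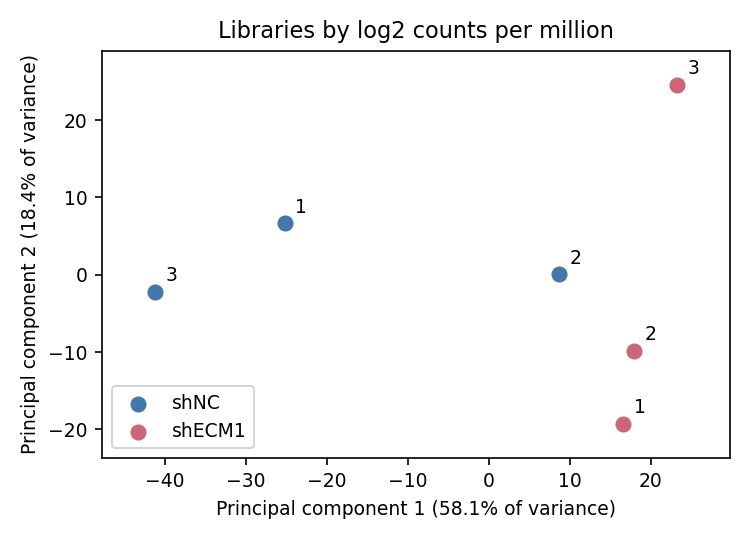
Principal components 1 (58.1% of variance) and 2 (18.4%) of log2 CPM, with 1 point per library and numbers giving the replicate. shNC replicate 2 lay at 8.64 on component 1, nearer to the shECM1 libraries (16.6 to 23.3) than to the other shNC libraries (-25.2 and -41.3).

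Across the transcriptome, edgeR's quasi-likelihood test called 0 of 12576 genes, with a smallest adjusted p of 0.0973. At an unadjusted p under 0.05, 2827 genes (22.5%) differed, 1782 lower and 1045 higher in shECM1. Leaving out 1 library gave between 1433 such genes (without shNC replicate 3) and 4748 (without shNC replicate 2). In 3068 genes (24.4%) every shECM1 library lay on 1 side of every shNC library, where chance gives 10% on average. Genes move together, so the share in 1 split can lie far from 10% without a group effect. It was not tested against chance. DESeq2 called 713 genes, 593 lower and 120 higher. limma-voom called 0, with 2776 at an unadjusted p under 0.05. edgeR with no count filter called 505. Without shNC replicate 2, edgeR called 3037 genes, 1799 lower and 1238 higher, and leaving out any other library gave 0. All 593 genes that DESeq2 called lower, and 119 of the 120 it called higher, were called in the same direction by edgeR without shNC replicate 2. Large differences lay mostly on the lower side, with 279 genes at a log2 fold change under -1 and 27 above 1.

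The genes with the smallest p-values on the lower side, uncalled by edgeR, were TJP3, EGR1, ABCA7, BCAM and HAP1. TJP3, a tight junction scaffold protein, was at 20.1 ± 5.77 CPM in shNC and 8.13 ± 0.859 in shECM1 (log2 fold change -1.30 ± 0.22 SE). EGR1, an immediate-early transcription factor, was at 207.1 ± 42.5 against 115.5 ± 5.93 CPM (-0.84 ± 0.14). The log2 fold changes of ABCA7, a lipid transporter, BCAM, a laminin receptor, and HAP1, a huntingtin-associated protein, were -0.78, -0.97 and -1.72. On the higher side the smallest p-values belonged to NDUFAF2, an assembly factor of respiratory complex I, FBXO4, MRPL1, SEC11C and BOLA2B. NDUFAF2 was at 27.2 ± 4.17 CPM in shNC and 43.3 ± 3.94 in shECM1 (0.67 ± 0.14 SE). FBXO4, MRPL1, a mitochondrial ribosomal protein, and SEC11C, a signal peptidase subunit, had log2 fold changes of 0.64, 0.60 and 0.61. BOLA2B, at 1.97, rested on low levels, with 0.501 ± 0.372 CPM in shNC and 1.91 ± 0.131 in shECM1. It also shares its sequence with a near-identical copy, and its value is uncertain. Each of these 10 genes had an edgeR adjusted p of 0.0973, and DESeq2 called 9 of them, while it gave BOLA2B no adjusted p.

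Among the genes DESeq2 called that met the naming rule, the largest fall was in ARC, an activity-regulated immediate-early gene, from 3.48 ± 1.55 CPM in shNC to 0.723 ± 0.143 in shECM1 (DESeq2 log2 fold change -2.27, adjusted p = 0.00131). OLFM1 (-1.95), the calcium channel TRPV4 (-1.78), NR4A1 (-1.76), HAP1 (-1.72) and INSIG1 (-1.69) followed. NR4A1, an immediate-early nuclear receptor, went from 30.5 ± 16.1 to 8.94 ± 1.59 CPM (DESeq2 adjusted p = 0.0212). INSIG1, a sterol-regulated membrane protein, went from 18.9 ± 9.73 to 5.85 ± 0.506 CPM (DESeq2 adjusted p = 0.000198). CORO6, the potassium channel KCNN4, B3GAT1 and the calcium-binding protein CALB2 had DESeq2 log2 fold changes from -1.66 to -1.69. The largest rise was in RGPD6 (1.87), which belongs to a family of near-identical copies and is uncertain. The monocarboxylate transporter gene SLC16A9 (1.17), the mitochondrial enzyme gene DMGDH (1.14), METTL8 (0.99), FAIM (0.84), SFXN4 (0.83), PIGW (0.82), GCFC2 (0.81), the hyaluronan synthase gene HAS2 (0.78) and the uracil-DNA glycosylase gene UNG (0.78) came next. All 20 were also called in the same direction by edgeR without shNC replicate 2.

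By gene list, 16 of the 32 lists tested were shifted lower in shECM1 and 3 were shifted higher by camera with the preset correlation. None of the 19 passed with an estimated correlation (adjusted p of 0.481 for 18 of them and 0.594 for the G2 and M phase list), and none with fry (adjusted p of at least 0.248). Their estimated correlations ran from 0.11 in p53 targets to 0.74 in immediate-early genes, above the preset 0.01. The calls of these lists therefore rest on the preset value. Without shNC replicate 2, fry passed 16 of the 19, 15 lower and 1 higher, all but the G2 and M phase (adjusted p = 0.0834), ribosomal protein (0.108) and nuclear respiratory chain (0.0618) lists. With an estimated correlation 0 of the 19 passed without that library either (adjusted p of at least 0.226). No member of any list was called by edgeR over all genes tested. Of 424 genes in the called lists, 4 belonged to more than 1.

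Immediate-early genes, transcribed within minutes of growth factor signalling, were shifted lower (camera adjusted p = 1.06e-08, and adjusted p = 0.481 with an estimated correlation). All 21 tested members had a negative log2 fold change, with a median of -0.71, and 15 passed when adjusted over the list alone. JUN was at 135.6 ± 34.2 CPM in shNC and 92.8 ± 7.59 in shECM1. FOS, chosen after its values were seen, was at 39.9 ± 15 against 19.1 ± 1.54 CPM. Genes of ERK pathway output and feedback were also shifted lower (adjusted p = 1.83e-05, and 0.481 with an estimated correlation), with 18 of 21 negative. Of these, 12 were lower and 1 higher when adjusted over the list alone. The receptor gene EPHA2 was at 570.8 ± 190 CPM in shNC and 334.5 ± 24.7 in shECM1, and IER3 at 561.7 ± 190 and 335.3 ± 23.8. MYC, a growth-promoting transcription factor chosen after its values were seen, went the other way in that list, at 332.6 ± 146 CPM in shNC and 538.2 ± 116 in shECM1. In shNC replicate 2, FOS was at 23.5 CPM and EPHA2 at 375.7, closer to the shECM1 libraries than to the other shNC libraries.

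Inflammatory lists that bear on CCL20 were shifted lower too by camera with the preset correlation. NF-kB targets had 24 of 28 members negative and 8 lower when adjusted over the list alone (camera adjusted p = 0.000182, and adjusted p = 0.481 with an estimated correlation). TNIP1, an inhibitor of NF-kB signalling, was at 149.4 ± 20.4 CPM in shNC and 124.1 ± 7.13 in shECM1, with 128.1 in shNC replicate 2. Of 31 chemokines and cytokines 18 were tested, and IL6 and CXCL10 had 0 counts in every library. The tested genes had 13 of 18 negative and 6 lower when adjusted over the list alone (adjusted p = 0.00254, and 0.481 with an estimated correlation). TGFB1 was at 74.2 ± 25.5 against 42.8 ± 4.05 CPM, whereas MIF was at 402.2 ± 87.2 against 373.8 ± 95.9. Chosen after their values were seen, CXCL8 had a log2 fold change of -0.73 ± 0.29 (SE), IL11 of -1.60 ± 0.39 and CXCL3 of 0.07 ± 0.28. STAT3 targets had 12 of 13 negative and 6 lower when adjusted over the list alone (adjusted p = 0.00122, and 0.481 with an estimated correlation). BCL2L1 and VEGFA had log2 fold changes of -0.21 and -0.28. The IL-17 receptor pathway had 10 of 11 negative and 1 lower when adjusted over the list alone (adjusted p = 0.0101, and 0.481 with an estimated correlation), with CEBPB at -0.37 and IL17RE at -0.38. These 11 were the tested part of 21 genes, of which S100A8 and PTGS2 had 0 counts in every library. TGF-beta targets had 13 of 20 negative, with 6 lower and 1 higher when adjusted over the list alone (adjusted p = 0.0324, and 0.481 with an estimated correlation). TGFBI and BHLHE40 stood at -0.25 and -0.74, and the call was lost without shNC replicate 3 (adjusted p = 0.0718) or shECM1 replicate 2 (adjusted p = 0.0528).

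Matrix and adhesion lists were shifted lower by camera with the preset correlation. The matrix and basement membrane list had 21 of 23 members negative, a median log2 fold change of -0.61 and 16 lower when adjusted over the list alone (camera adjusted p = 8.21e-08, and adjusted p = 0.481 with an estimated correlation). LAMB3, a laminin chain, was at 704.6 ± 186 CPM in shNC and 458.7 ± 49.7 in shECM1, and AGRN, agrin, at 391 ± 58.5 and 272.4 ± 15.6. In shNC replicate 2, LAMB3 was at 511.9 CPM and AGRN at 324.2, below the other shNC libraries and above every shECM1 library. LAMA5, another laminin chain, chosen after its values were seen, was at 370.8 ± 64.3 against 227.6 ± 11.1. All 23 integrin and adhesion genes were negative, and 14 were lower when adjusted over the list alone (adjusted p = 6.57e-08, and 0.481 with an estimated correlation). The integrin gene ITGB4 was at 1476 ± 429 CPM in shNC and 845.2 ± 85.8 in shECM1, while ITGB1 was at 866.8 ± 95.2 and 771.8 ± 118. Epithelial genes (18 of 23 negative, 4 lower when adjusted over the list alone, adjusted p = 0.00236) and mesenchymal genes (12 of 14 negative, 2 lower, adjusted p = 0.00411) were both shifted lower, each with adjusted p = 0.481 with an estimated correlation. KRT8 and KRT18 had log2 fold changes of -0.27 and -0.29, and VIM and S100A4 of -0.40 and -0.11.

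Fixed markers of other cell types were measured beside these lists. The count filter left 5 of 15 fibroblast, 4 of 18 immune, 4 of 13 endothelial and 4 of 12 embryonic kidney markers. PDGFRA, PTPRC and KDR, markers of the first 3 types in turn, had 0 counts in every library. Whether the tested members came from cells of these types was not tested. Of the fibroblast markers, 5 were tested, all were negative, and COL6A1, COL6A2 and COL1A1 were lower when adjusted over the list alone (camera adjusted p = 0.00122, and adjusted p = 0.481 with an estimated correlation). COL6A1 was at 168.3 ± 49.3 CPM in shNC and 83.7 ± 2.77 in shECM1, and COL6A2 at 43.3 ± 16 and 17.2 ± 3.63. The 4 tested immune markers were all negative, and CD68, a lysosomal protein, was at 121.1 ± 53.2 against 58.6 ± 15.6 CPM and LYZ at 10.9 ± 5.37 against 5.57 ± 0.957. In shNC replicate 2, COL6A1 was at 117.6 CPM and CD68 at 68.9. Of the immune markers, 3 were lower when adjusted over the list alone. The 4 endothelial markers tested were all negative, with 0 passing, and of 4 embryonic kidney markers 3 were negative and 1 was lower when adjusted over the list alone. These 3 lists were too short for camera.

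Genes of sterol synthesis and of glycolysis and hypoxia were shifted lower by camera with the preset correlation. The cholesterol synthesis list had 22 of 25 members negative, a median of -0.40 and 9 lower when adjusted over the list alone (camera adjusted p = 1.05e-05, and adjusted p = 0.481 with an estimated correlation). SREBF2, the sterol-responsive transcription factor, was at 242.2 ± 42.5 CPM in shNC and 180.3 ± 13.6 in shECM1, and FDFT1, squalene synthase, at 223.7 ± 66.1 and 153.5 ± 8.52. In shNC replicate 2 they were at 193.3 and 155.4 CPM, within the range of the shECM1 libraries. Of the hypoxia and glycolysis genes, 28 of 29 were negative and 6 were lower when adjusted over the list alone (adjusted p = 4.26e-06, and 0.481 with an estimated correlation). The glycolytic enzyme genes GAPDH and PGK1 had log2 fold changes of -0.21 ± 0.13 and -0.30 ± 0.13 (SE).

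The 3 lists shifted higher held genes of protein synthesis, respiration and protein folding. Of 50 ribosomal protein genes, 49 had a positive log2 fold change, with a median of 0.18 (camera adjusted p = 4.35e-08, and adjusted p = 0.481 with an estimated correlation). RPS3 and RPS2 had log2 fold changes of 0.05 and 0.15. Nuclear genes of the respiratory chain were positive in 34 of 38 cases, with a median of 0.18 (adjusted p = 2.26e-05, and 0.481 with an estimated correlation). ATP5F1B, an ATP synthase subunit, was at 0.09, and UQCRC1, a complex III subunit, at -0.19. Heat shock genes were positive in 12 of 16 cases, with a median of 0.23 (adjusted p = 0.00112, and 0.481 with an estimated correlation). The mitochondrial chaperonin gene HSPD1 was at 749.7 ± 127 CPM in shNC and 989.8 ± 109 in shECM1, and HSP90AB1 at 1659 ± 142 and 1923 ± 10.2. In shNC replicate 2 they were at 895.3 and 1822 CPM, above the other shNC libraries. In each of these lists 0 members passed when adjusted over the list alone. The 13 mitochondrially encoded genes were not called as a list (median -0.11, camera adjusted p = 0.7).

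The G2 and M phase list and the p53 list gave calls that rested on single libraries. Genes of G2 and M phase had 22 of 29 members negative and a median of -0.17, with 0 passing when adjusted over the list alone (camera adjusted p = 0.0107, and adjusted p = 0.594 with an estimated correlation). TOP2A and MKI67 had log2 fold changes of -0.21 and -0.40. The call was lost without shNC replicate 3 (adjusted p = 0.155) or shECM1 replicate 3 (adjusted p = 0.332). p53 targets had 14 of 22 negative and 9 lower when adjusted over the list alone (adjusted p = 0.0321, and 0.481 with an estimated correlation). GDF15 and GADD45A stood at -0.44 and -0.52, and the call was lost without shNC replicate 3 (adjusted p = 0.0674) or shECM1 replicate 3 (adjusted p = 0.084).

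The remaining lists were not called by camera. Wnt targets (median log2 fold change -0.07, adjusted p = 0.417), the AKT and mTOR pathway (-0.06, 0.228) and S phase genes (0.01, 0.347) had 0 members passing when adjusted over the list alone. Interferon response genes (-0.07, 0.336) had 5 lower members by that count. Antigen presentation (-0.14, 0.138), the integrated stress response (-0.02, 0.443), the unfolded protein response (0.11, 0.139) and replication histones (-0.08, 0.347) had 0. NRF2 targets (-0.11, 0.308) had 1 lower. Among intestinal cell types, stem cell genes (0.15, 0.159) and enterocyte genes (-0.28, 0.308) had 0, and secretory lineage genes (-0.42, 0.136) had 3 lower. Nuclear noncoding RNAs were not analysed here.

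**Figure D3:**
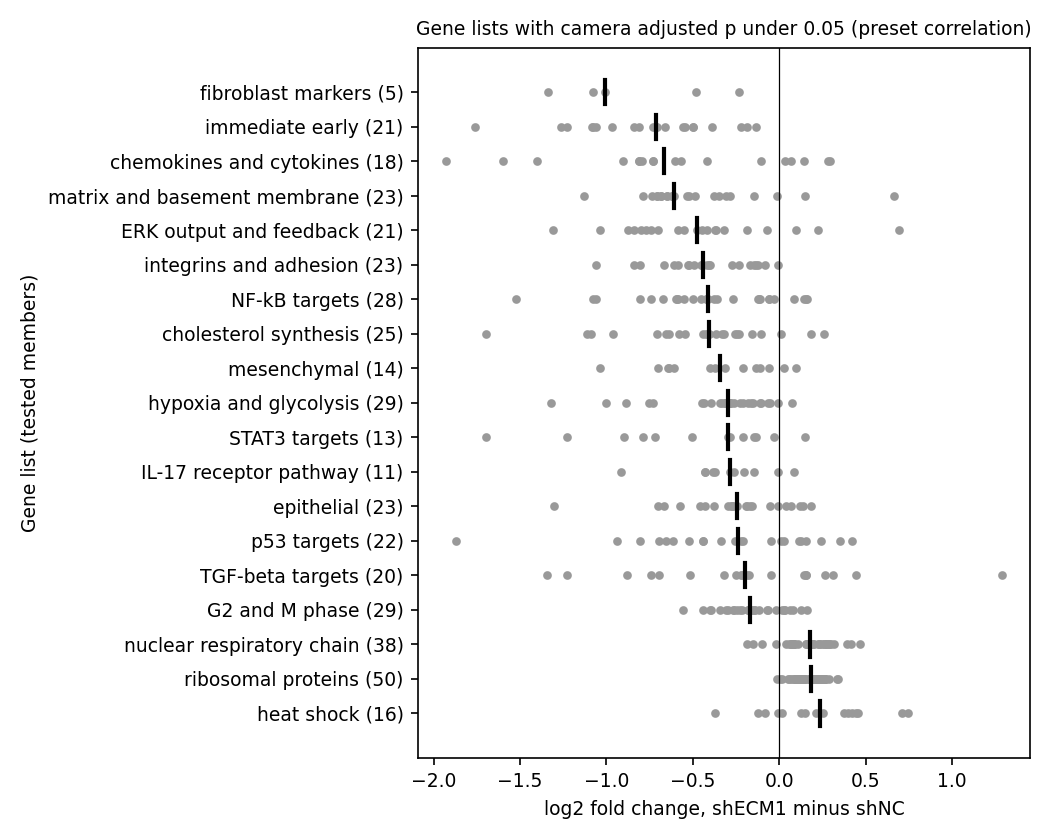
Log2 fold change (shECM1 minus shNC) of each tested member, as grey points, of the 19 gene lists with a camera adjusted p under 0.05 with the preset correlation, with black bars at the medians and tested members in parentheses. Medians ran from -1.01 in fibroblast markers to 0.23 in heat shock genes, and all 21 immediate-early genes lay below 0.

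The fold changes also followed GC content. Across 12502 genes, which are not independent replicates, Spearman's correlation of the log2 fold change with transcript GC content was -0.38. The median log2 fold change went from 0.15 in the lowest of 10 equal bins of genes by GC content to -0.21 in the highest. The slopes of level against GC content were 0.12, -0.0096 and 0.12 log2 units per 10 GC points in shNC and -0.14, -0.13 and 0.05 in shECM1. A two-sided exact permutation test of the slopes gave p = 0.2, and as 3 against 3 allows no less than 0.1, it could not decide whether the groups differed. With a GC offset, chosen after seeing the data, edgeR still called 0 genes.

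**Figure D4:**
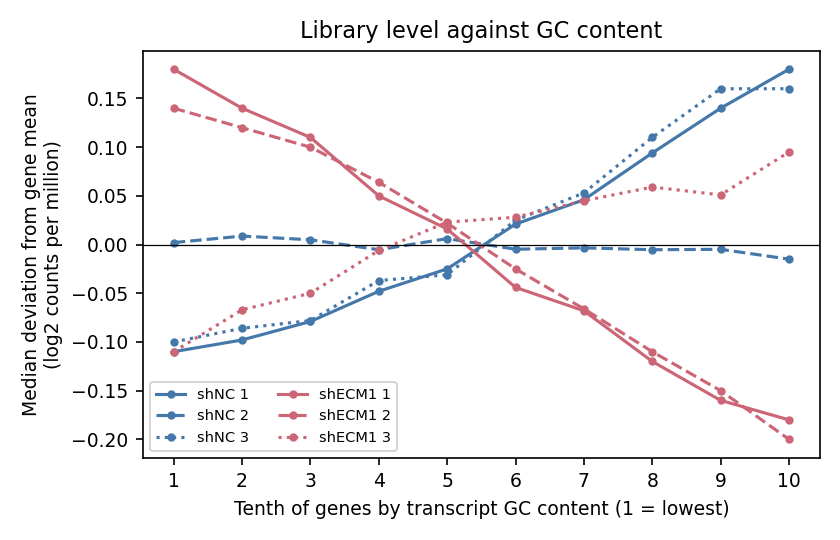
Median deviation from the gene mean (log2 CPM, vertical axis) against transcript GC content in 10 equal bins of genes, with 1 line per library. shNC replicates 1 and 3 (slope 0.12 each) and shECM1 replicates 1 and 2 (-0.14 and -0.13) sloped in opposite directions, shNC replicate 2 was flat (-0.0096) and shECM1 replicate 3 sloped upward (0.05).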

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

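The GC offset, the robust and non-legacy dispersion fits and the combined settings were chosen after the data were seen. The count of called genes was 0 in edgeR under every scaling, the stricter filter, both fold change minimums, limma-voom, the GC offset and the robust and non-legacy dispersion fits. It was 505 (42 higher, 463 lower) with no count filter and 713 (120 higher, 593 lower) with DESeq2, for which the cause was not tested. Leaving out 1 library gave 0 to 3037 genes, 0 to 1238 higher and 0 to 1799 lower, and only leaving out shNC replicate 2 gave any. Leaving out that library together with the GC offset gave 3281 (1497 higher, 1784 lower), and together with DESeq2 it gave 2680 (1078 higher, 1602 lower). Leaving out the control library nearest to the knockdown widens the difference by construction, so these counts are not independent evidence.

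The log2 fold change of ECM1 was -1.58 with no count filter (adjusted p = 0.0139), -1.58 with DESeq2 (0.0256), -1.76 with the GC offset and without shNC replicate 2 (0.00187) and -1.89 with DESeq2 and without shNC replicate 2 (1.17e-14). Leaving out 1 library gave -1.88 to -1.24, with adjusted p from 0.000192 to 0.376. That of CCL20 was -0.90 with no count filter (0.0486), -0.90 with DESeq2 (0.0246), -1.37 with the GC offset and without shNC replicate 2 (0.00265) and -1.17 with DESeq2 and without shNC replicate 2 (1.24e-05). Leaving out 1 library gave -1.16 to -0.50, with adjusted p from 0.00251 to 0.424. Over 29 named genes and their alternatives, 541 values held 0 reversals. In 400 the call was as in the main test and in 141 it passed the threshold. All of these genes but ECM1 and CCL20 were chosen by their values in these data, so the lack of reversals says little.

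The count of called lists was 0 (0 higher, 0 lower) with an estimated inter-gene correlation and 0 (0 higher, 0 lower) with fry. Without shNC replicate 2, fry gave 22 lists (1 higher, 21 lower), among them 16 of the 19, and an estimated correlation gave 0 (0 higher, 0 lower). Leaving out 1 library gave 16 to 22 lists, 3 higher each time and 13 to 19 lower. Over the 19 lists, 341 values held 0 reversals, and 67 fell short of the threshold. Because these lists were chosen by their main call, the lack of reversals says little here too. The IL-17 receptor list lost its call with the GC offset and without shNC replicate 2 (adjusted p = 0.0671).

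With the replicate number as a block, edgeR called 0 genes, with 2414 at an unadjusted p under 0.05. Deviations of same-numbered libraries from their group means correlated at -0.07, -0.046 and -0.18 across genes, which gave no sign of pairing. With 3 libraries in each group these deviations depend on each other, so the values cannot exclude pairing. The groups' ranges of depth overlapped, and genes removed by the count filter were not tested.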

Other observations

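The tests of the GC offset on the lists and on the fold changes, of a wrong label and of other splits, and all gene families in the next paragraph, were chosen after results had been seen.

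Most tested members of 5 gene families shared a direction in shECM1, but each family missed 0.05 with an estimated correlation. fry, which does not compare a family with other genes, gave unadjusted p = 0.0178 for mitochondrial ribosomal proteins, 0.00788 for the proteasome, 0.0167 for collagens, 0.0168 for semaphorins and 0.0717 for keratins. Mitochondrial ribosomal protein genes had a positive log2 fold change in 73 of 76 cases, with a median of 0.22 and 30 higher at an unadjusted p under 0.05. Camera with the preset correlation gave p = 7.92e-14, and p = 0.0921 with an estimated correlation. Proteasome subunit genes were positive in 33 of 37 cases, with a median of 0.14 (camera p = 9.53e-05, and p = 0.0794 with an estimated correlation). Collagen genes were negative in 12 of 13 cases (median -0.62, camera p = 7.89e-06, and p = 0.0604 with an estimated correlation). Semaphorin genes, which encode guidance cues, were negative in 12 of 15 cases (median -0.58, p = 0.000917, and p = 0.0536 with an estimated correlation). Keratin genes were negative in 16 of 17 cases (median -0.29, p = 4.79e-05, and p = 0.183 with an estimated correlation). Of the tested members, 8 collagen, 4 keratin and 3 proteasome genes also belonged to the fixed lists, so those families partly repeat them. The families were picked because their members had been seen to move, so these p-values are too small.

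The first pattern is that shNC replicate 2 lay near the shECM1 libraries, at 0.8 of the way from the other shNC libraries to the shECM1 mean on principal component 1. The position was 0.81 after the GC offset, so a smooth GC trend did not account for it. That trend was modest in size, which made a large move unlikely beforehand, so this is weak evidence on GC bias. A knockdown library under the wrong label stays open, because over genes picked without it and without 1 shECM1 library, shNC replicate 2 had median positions of 0.766, 0.805 and 0.733 and the left-out shECM1 library 0.877, 0.956 and 0.837 (smallest gap 0.105, range among the left-out libraries 0.119). ECM1 itself was at 19.0 CPM in shNC replicate 2, above the 8.41 to 14.8 CPM of the shECM1 libraries. It lay at 0.797 of the way to the shECM1 mean, near the median of 0.8 over genes called without that library. That match shows only that ECM1 was as intermediate as other genes in this library. As 1 gene in 1 library, ECM1 cannot decide for or against a wrong label. Pearson correlations of shNC replicate 2 were 0.9905, 0.9917 and 0.9883 with shECM1 replicates 1, 2 and 3. They were lower with shNC replicates 1 and 3, at 0.9842 and 0.9756. A mixture of RNA from both groups in 1 proportion may also account for the place of shNC replicate 2. It cannot be told apart from control cells in another state, which was not tested. A mixture in 1 proportion predicts the same median position for genes called lower and genes called higher without the library. These differed by 0.095 on average, with the same sign in all 6 pairs of libraries (0.0639 to 0.122). The mean fell short of the size set beforehand for arguing against a mixture, so the test could not decide. Medians by list ran from 0.41 in 5 nuclear respiratory chain genes and 0.54 in 9 ribosomal protein genes to 1 in 10 G2 and M phase genes and in 3 other lists. The error of that spread was not tested.

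The second pattern is the trend of fold changes with GC content, with a Spearman correlation of -0.38 across genes. Fold changes with and without the GC offset correlated at 0.949 across genes, so a smooth trend on GC content made up only part of them. A high value was nearly fixed by the modest size of the trend already seen. It is therefore not separate evidence on GC bias as the whole cause of the fold changes. The 19 list calls were all kept in the same direction with the GC offset, so removing a smooth GC trend did not remove them. With fold changes so alike before and after the offset, this was likely beforehand. It is not separate evidence on GC bias as their whole cause either. ECM1 went from -1.58 to -1.46 and CCL20 from -0.91 to -1.08 with the offset. Whether the trend itself is technical or follows the hairpin stays open, since 2 of 3 libraries in each group carry it.

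The third pattern is the number of calls against other splits of the 6 libraries into 3 and 3, of which there are 10, too few for a share under 0.05. The edgeR count says nothing here, since the real split gave 0 and all 10 splits therefore gave at least as many (highest other split 1). At an unadjusted p under 0.05 the real split gave 2827 genes and the highest other 2127. The real split gave 713 in DESeq2 (highest other 68, with 1 split as large, the real one). The real split gave 19 lists, and 2 splits gave as many, the real one included, with 21 in the split that exchanged shNC replicate 2 for shECM1 replicate 3. Exchanging it for shECM1 replicate 1 or 2 gave 18 lists each, and splits that separated shNC replicates 1 and 3 gave 1 to 7. A high list count therefore came with shNC replicates 1 and 3 together, whichever library joined them.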
